A study of Mus musculus with 12 samples.

How the data were processed

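Lung RNA from wild-type mice was measured on 12 Affymetrix whole-genome mouse arrays. The labels give 4 groups of 3 arrays: control, radiation (25 Gy, lungs taken at 6 weeks), simvastatin (10 mg/kg by repeated intraperitoneal injection) and both treatments, called the combined group below. Simvastatin blocks HMG-CoA reductase, the enzyme that limits cholesterol synthesis. Each array was put in its group by its title and treatment label, never by its values. Arrays are named by group and replicate number, for example control 3. All 12 arrays carry the same description, which calls the tissue that of a control animal, irradiated groups included, so that field was not used. The age range given for the control animals is not the same as that of the other groups. In every comparison with control, age therefore cannot be told apart from treatment. The controls also enter the interaction and irradiated minus unirradiated. The labels describe total RNA extracted with Trizol and biotin-labelled cRNA.

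The values are deposited log2 intensities, and the submitters' notes name MAS5 and GCRMA as their processing. Their versions and the background settings are not given in the sources used here. The table held 45101 probe sets, and values ran from 0.817 to 16.3 on the log2 scale. Array medians lay between 4.42 and 5.12, so the arrays were not at a common median. The number of arrays limits the precision. Array values carry no genome build, so no coordinates are given.

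Of the probe sets, 64 Affymetrix controls were left out. The platform annotation gave 1 gene symbol to 34958 probe sets, several symbols to 932 and none to the others, and gene tests used those with 1 symbol. Of these, 34754 had an Entrez identifier that matched the RefSeq table. A probe set was kept when it lay above the median of all values, log2 4.85, on at least 3 of 12 arrays, which left 20073. The probe set with the highest mean stood for its gene, which gave 11602 genes. Another 3384 kept probe sets without a single symbol were tested apart.

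The test fixed beforehand treated 12 arrays as 12 samples. When the data were examined, simvastatin 1 and simvastatin 3 were found to be near-identical. The SD of their log2 differences was 0.118 over 10342 probe sets with a mean above 9, against 0.336 or more in the 63 pairs outside a group of 3 near-identical arrays. Their mean was therefore counted as 1 sample, which left 11 samples, 2 of them simvastatin, and 7 residual degrees of freedom. The third near-identical array is combined 3, which has another label and was kept apart. If it holds the same RNA, the samples and degrees of freedom are overcounted and that RNA stands on both sides of the interaction and of irradiated minus unirradiated. This choice was made after exploratory fits had been seen. The count of genes was 0 in every comparison with either choice, but 5 list calls of the fit with 11 samples ended in the fit with 12 arrays, and the report names them. Nothing in the labels says that the arrays come from separate animals, so every p-value measures the spread between these samples.

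The 6 comparisons were radiation minus control, combined minus radiation, simvastatin minus control, combined minus control, the interaction of radiation with simvastatin, and irradiated minus unirradiated. limma 3.58.1 in R 4.3.3 fitted group means with lmFit and moderated the variances with eBayes and a trend on the mean. The p-values are two-sided and were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. A gene's error is the standard error (SE) of its log2 difference, and group values carry the SD of arrays. Where single quantities were compared, an exact permutation test over all splits was run on means. With 3 against 3 samples, or 2 against 3, its two-sided p cannot fall under 0.1.

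Gene lists were written from general knowledge before any value was seen. They cover p53 target genes, Nrf2 target genes, sphingolipid metabolism and S1P receptors, cholesterol biosynthesis, and extracellular matrix and fibrosis. Inflammatory mediators, cell cycle, interferon-stimulated genes, MHC class II, circadian clock, immediate early and heat shock genes, and the glucocorticoid and fasting response were also listed. Cell and tissue markers covered endothelium, alveolar type 1 and type 2 cells, airway epithelium, macrophages, T and NK cells, B and plasma cells, neutrophils, mast cells, erythroid cells, skeletal muscle, cardiac muscle and adipose tissue. Of these 26 lists 25 were tested, since the mast cell list had 2 measured members of 12 and the minimum was 3. The results of 1 tested list are not reported here, but it stays in the counts of lists and in the adjustment. Each was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists. Another 4 lists, for squamous epithelium, brown fat, thymocytes and ciliated cells, were added after the data were seen and were not tested. Their levels are given as medians of members.

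On simulated data, 200 of 11602 genes were changed in each of 20 draws, with independent noise for each gene and sample. The fit recovered 29.0% of changes of log2 1 and 71.0% of changes of log2 2 in a comparison of 3 with 3 samples, with 4.92% false among the calls. For simvastatin against control, recovery was 20.6% and 65.0%. The real arrays shared differences across many genes, with 44.9% of the variance on the first principal component. The simulated recovery and false share therefore need not hold for them. Lists of 30 genes with no change but a correlation of 0.3 were called in 43.5% of 200 draws at the preset correlation, and in 4.5% with the correlation estimated from the data. For this reason the p-value with an estimated correlation stands beside every list called. With a shift of 0.5 at that correlation the estimated test still called 72.0%. These shares count 1 list at a time at an unadjusted p under 0.05, with the genes outside it simulated as independent. The tested lists had 3 to 29 measured members and were adjusted over 25 lists, so the 72.0% does not carry over to them.

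The rule for naming genes was fixed beforehand. It took the genes with the largest changes among those past the threshold, or, where none passed, the 5 with the lowest p. It added up to 4 members of each list with the lowest p, of which the text names some, and all p53 and cholesterol genes that passed. Cdkn1a, chosen before the data were examined as a check of the labels, is given throughout. The genes of the sexes Xist, Eif2s3y and Kdm5d were checked as well. The other check genes, the added lists and the arrays left out by level were chosen after values had been seen.

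Alternatives fixed before the data were examined were quantile normalization, median centring, no filter, a stricter filter at the 70th percentile (log2 8.24), the mean of a gene's probe sets, probe sets tested apart, no variance trend, robust variances, array weights, a fit of the compared groups alone, replicate number as a block, a 1.5-fold threshold, a floor at the 25th percentile (log2 2.38) and leaving out each array in turn. For lists they were an estimated correlation and limma's fry. The test with 12 separate arrays was kept as an alternative. Others chosen after the data were seen were leaving out 3 arrays whose Cdkn1a level goes against the label, leaving out 2 arrays with Y-linked transcripts, a block for the sides of the first principal component, array weights by the gene-by-gene method, and control and combined arrays alone with the replicate number as a block. Median centring for the lists and the medians of lists and the correlation of effects without each array were added then too. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

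The share of the radiation change left with simvastatin was measured over 9 choices of 1 left-out radiation array and 1 left-out control array. Genes were chosen without these arrays, the 500 of lowest p in each, and measured with them. The plan had been to use genes past the threshold, which 6 of the 9 choices lacked, so the 500 genes replaced them and the radiation change on the left-out arrays is given instead of a percentage. A null of 100 simulated draws from the arrays' spread was made for the correlation of the radiation and drug effects, because both use the radiation arrays. No array was relabelled or left out of the tests. Probe sets with several symbols were not assigned to genes.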

Results

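The study asked whether simvastatin, a cholesterol-lowering drug, limits vascular leak and inflammation in mouse lungs injured by radiation. RNA levels were measured on 12 arrays, 3 for each of 4 labelled groups: control, 25 Gy of radiation with lungs taken after 6 weeks, simvastatin at 10 mg/kg, and both treatments together, here the combined group. Tests covered 11602 genes, and all values are log2 intensities. Simvastatin 1 and simvastatin 3 were near-identical and entered the tests as 1 sample, so n = 3 for each group except simvastatin, where n = 2. Nothing in the labels says that the arrays come from separate animals, and p-values measure the spread between these samples. The labels give the controls another age range than the other groups. In comparisons with control, age and treatment therefore cannot be told apart.

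The check genes of radiation contradicted the label of 3 arrays. Cdkn1a (Entrez gene 12575) encodes p21, which stops the cell cycle when p53 is active after DNA damage. It stood at 10.2 and 10.7 on control 1 and control 2 but at 13.0 on the array labelled control 3, beside 13.1 to 13.4 on the radiation arrays. Combined 1 and combined 2 both read 13.2, and the array labelled combined 3 read 11.2. The array labelled simvastatin 2 read 13.4, while the other two simvastatin arrays both read 11.1. Eda2r, a receptor gene that p53 switches on, was 7.49 on control 3 against 3.54 and 3.91 on the other controls, 4.33 on combined 3 against 7.67 and 7.75, and 8.28 on simvastatin 2 against 4.15 and 4.75. Every direction below that involves these groups rests on the labels as given, in which 1 control array, 1 combined array and 1 simvastatin array carry p53 target levels of the opposite kind. Hmgcs1, a gene of cholesterol synthesis that cells raise when statins lower their sterols, lay between 12.8 and 13.3 on all 12 arrays.

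**Figure D1:**
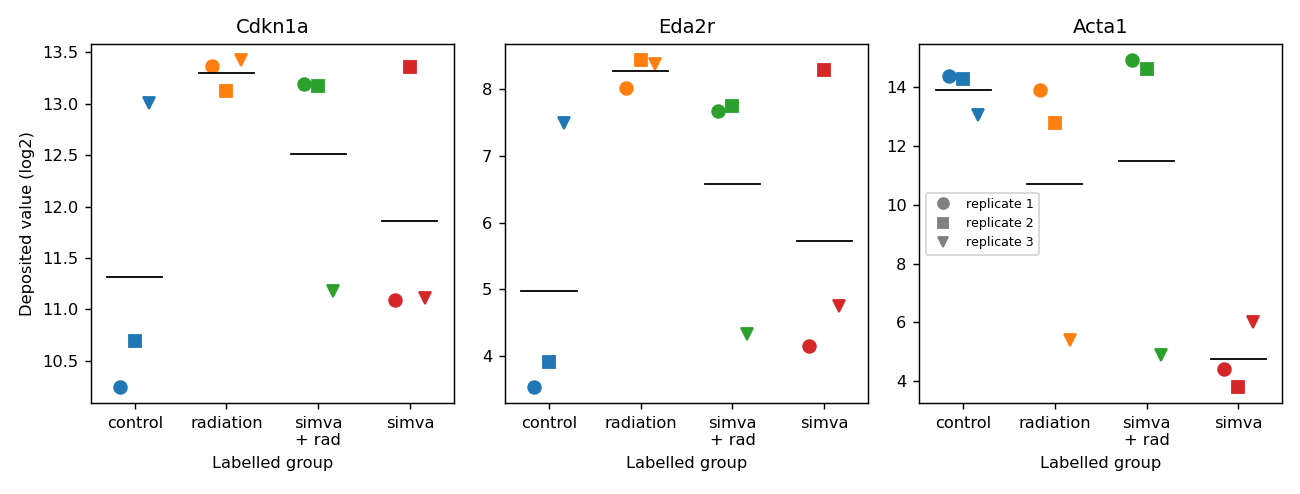
Log2 intensity of Cdkn1a, Eda2r and Acta1 on each of the 12 arrays, by labelled group, with the mean of each group as a line. Acta1 encodes skeletal muscle actin.

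Other differences between arrays cut across the groups. The Y-linked genes Eif2s3y and Kdm5d read 10.2 and 8.83 on control 3 and 10.4 and 8.9 on radiation 1, and Eif2s3y was between 2.75 and 3.46 elsewhere. Xist, which female cells transcribe from the silenced X chromosome, read 2.45 on control 3 and 2.5 on radiation 1, 12.3 on radiation 2 and 13.6 to 14.5 on the other arrays. Skeletal muscle actin, Acta1, was 12.8 to 14.9 on 7 arrays and 3.81 to 6.03 on radiation 3, combined 3 and all simvastatin arrays. Krt4, a keratin of squamous lining such as the oesophagus, was 15.2 on control 1 and control 2, 8.17 on control 3, 13.1 on radiation 1, 13.8 and 15.5 on combined 1 and combined 2, and at most 3.07 on the other 6 arrays. Ucp1, the heat-producing protein of brown fat, was 12.9 on control 1, 12.3 on control 3, 8.74 on radiation 2, 12.6 on combined 1 and 10.5 on combined 2, and no higher than 2.32 on the rest. Cd8b1, a marker of cytotoxic T cells and thymocytes, read 12.7 on control 1 and 8.9 on combined 1. The first principal component held 44.9% of the variance and set control 3, radiation 1 and radiation 2, at -102, -107 and -140, apart from the other 9 arrays, which lay between 19.7 and 81.6.

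**Figure D2:**
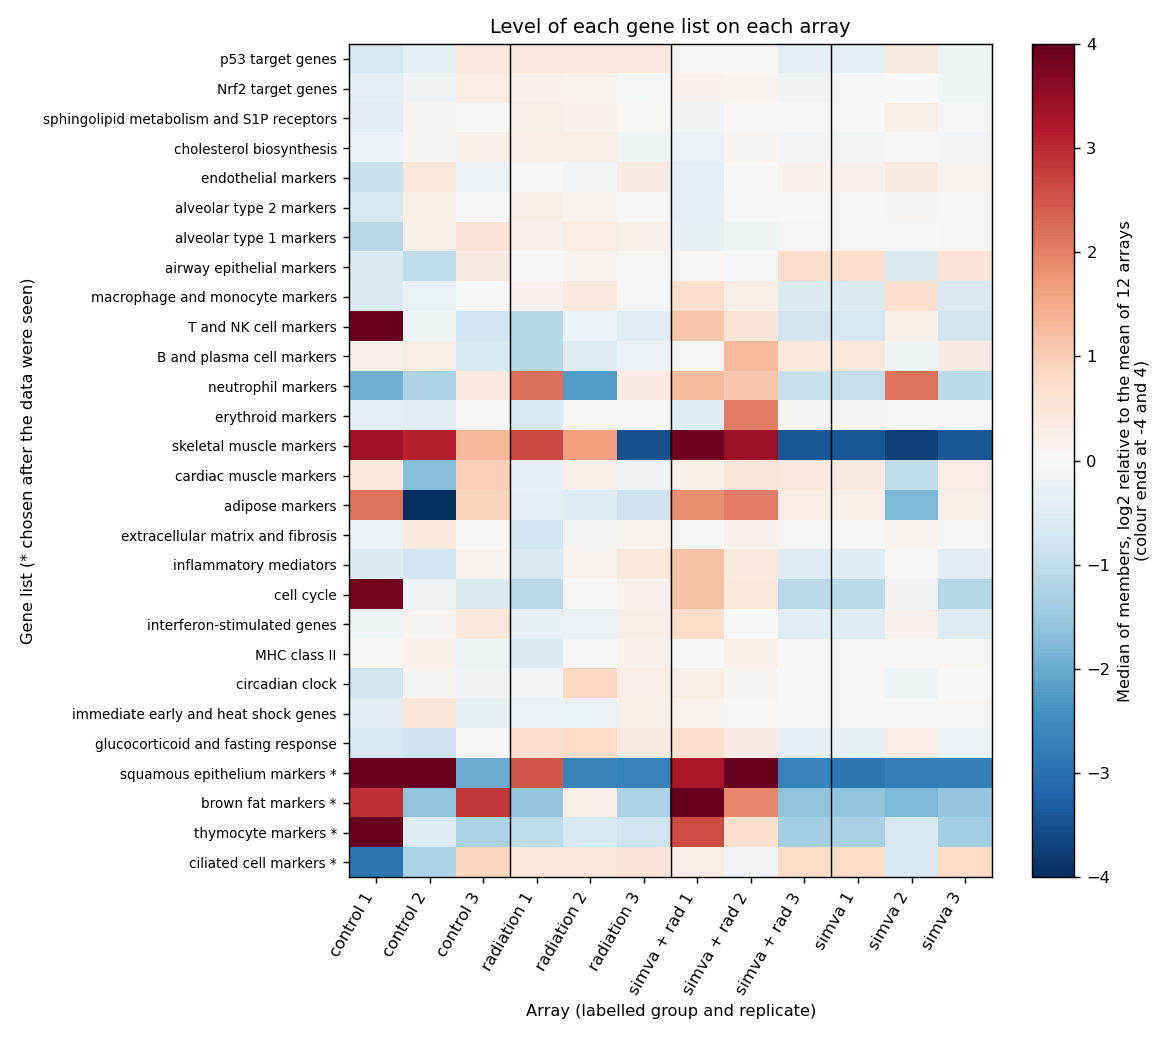
Median log2 level of the members of each gene list on each array, relative to the mean of the 12 arrays, with the colour scale ending at -4 and 4. An asterisk marks lists chosen after the data were seen.

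Radiation minus control asked what 25 Gy changed in the lung at 6 weeks. By limma 0 of 11602 genes passed, with 600 at an unadjusted p under 0.05 where 580.1 were expected by chance, and the lowest adjusted p was 0.751. The same number was expected in each of the other comparisons, and their counts given below all lay under it. Why they did was not tested. The tissue factor gene F3, which starts blood clotting, was 12.07 ± 0.32 (SD, n = 3) after radiation and 10.99 ± 0.26 in controls, a difference of 1.08 ± 0.20 (SE). Mbd1, a reader of methylated DNA, differed by 0.96 ± 0.16, the glucocorticoid-induced Tsc22d3 by 1.76 ± 0.34, the amino acid transporter gene Slc38a4 by 1.64 ± 0.33, and Cth, which makes cysteine and hydrogen sulphide, by 1.28 ± 0.26. Each of these 5 genes had a limma adjusted p of 0.751, and they are the 5 of lowest p. The exact permutation test gave Cdkn1a a two-sided p of 0.1 for a difference of 1.99, with 13.30 ± 0.16 after radiation and 11.31 ± 1.48 in controls, and the mean of the p53 list a p of 0.1 for 0.70. That is the lowest p that 3 against 3 arrays allow, and the array labelled control 3 narrowed the difference.

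Of 25 lists 11 passed camera at the preset correlation, and 0 of them passed with an estimated correlation or by the direction test of fry. The glucocorticoid and fasting response rose by a median of 1.02, with 12 of 12 members above 0 (adjusted p = 6.1e-08; adjusted p = 0.434 with an estimated correlation). None of its members passed over all genes, but 6 did when adjusted over the list alone. Among them were Tsc22d3, Fam107a, an actin-bundling stress gene, at 3.56 ± 0.79, the stress kinase gene Sgk1 at 0.61 ± 0.18 and the steroid-responsive transcription factor gene Klf9 at 0.58 ± 0.17. On single arrays this list stood below the mean of 12 arrays on control 1 and control 2, at -0.67 and -0.83, at -0.025 on control 3, and at 0.63, 0.76 and 0.35 on the radiation arrays. fry's test for change in either direction gave this list alone an adjusted p below the threshold, 0.0364.

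The p53 target genes rose by a median of 0.56, with 22 of 25 members above 0 (adjusted p = 0.000883; adjusted p = 0.609 with an estimated correlation). Eda2r differed by 3.30 ± 1.32, the death receptor gene Fas by 0.56 ± 0.22 and the stress sensor gene Sesn2 by 0.88 ± 0.36, and 0 members passed over the list alone. The sphingolipid and S1P receptor genes, which shape the vascular barrier, rose by 0.22 (adjusted p = 0.0355; adjusted p = 0.609 with an estimated correlation), with Sgms1, a sphingomyelin synthase gene, at 0.95 ± 0.26 and Sphk1, which makes the barrier lipid S1P, at 1.57 ± 0.49. Over the list alone 0 members passed, and without control 1 the median of this list was 0.083. Endothelial markers beside them had a median of 0.27 without passing (adjusted p = 0.0924), and ciliated cell markers, a list added later, a median of 1.58.

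Several lists of immune and proliferating cells fell, each with adjusted p = 0.609 with an estimated correlation. T and NK cell markers fell by 1.57 with 16 of 16 members below 0 (adjusted p = 2.7e-05), and Cd247, the signalling chain of the T cell receptor, was at -2.22 ± 1.29. Cell cycle genes fell by 1.30 with 22 of 22 members below 0 (adjusted p = 6.1e-08), and the replication helicase gene Mcm3 was at -1.08 ± 0.53. The thymocyte markers moved with them at a median of -2.29, and control 1 alone held T and NK markers at 4.32, cell cycle genes at 3.81 and thymocyte markers at 6.16 above the mean of 12 arrays. B and plasma cell markers fell by 0.67 (adjusted p = 3.77e-05), with the complement receptor gene Cr2 at -1.23 ± 0.51. Skeletal muscle markers fell by 2.69 (adjusted p = 0.00249), with the fast-fibre gene Actn3 at -3.01 ± 1.97, while squamous epithelium markers had a median of -3.43 and brown fat markers of -2.01. For all of these lists 0 members passed over the list alone. Without control 1 the median was -0.043 for T and NK markers and 0.029 for cell cycle genes. It was -0.29 for B and plasma cell markers without radiation 1 and -0.39 for skeletal muscle without radiation 3.

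Another 3 lists passed downward, each with adjusted p = 0.609 with an estimated correlation, and their medians rose above 0 under median centring because the median of all genes rose with them. They stayed below that median and were still called downward. Median centring moved the median of all genes to 0.36 in this comparison, from 0.084 as deposited, and to -0.45 for combined minus radiation, -0.0033 for simvastatin minus control, -0.082 for combined minus control, -0.45 for the interaction and 0.15 for irradiated minus unirradiated. Extracellular matrix and fibrosis genes had a median of -0.16 as deposited (adjusted p = 0.0355) and 0.029 after centring, or -0.24 and -0.33 relative to all genes, although the crosslinking enzyme gene Lox was at 1.98 ± 0.50 and the growth factor gene Ccn2 at 1.02 ± 0.29. Interferon-stimulated genes went from -0.26 (adjusted p = 0.00565) to 0.018, or -0.34 relative to all genes both times, with the antiviral GTPase gene Igtp at -0.78 ± 0.31. MHC class II genes, which present antigen, went from -0.20 (adjusted p = 0.00565) to 0.072, or -0.29 relative to all genes both times, with H2-Oa at -1.04 ± 0.53. For these lists too 0 members passed over the list alone, and without 1 array they lay above 0 as deposited: matrix genes at 0.076 and MHC class II genes at 0.038 without radiation 1, and interferon-stimulated genes at 0.0025 without control 3. Cholesterol biosynthesis did not pass (adjusted p = 0.563): its median was 0.058, camera pointed down, and its members diverged, with Pmvk at 1.39 ± 0.41 and Dhcr7 at -0.82 ± 0.35. The erythroid list, which did not pass either, had a median of 0.0043 and a mean of -0.013.

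Of the 11 calls, 3 were kept in all 14 other settings with the preset correlation: p53 target genes, B and plasma cell markers, and the glucocorticoid and fasting response, while each of the others ended in at least 1 and the sphingolipid call in 7. Leaving out 1 array changed the median by over 1.5 times for 8 of the 10 called lists reported and changed its sign for 4. The T and NK and cell cycle calls ended without control 1, the skeletal muscle call ended without radiation 3, and the gene count went from 0 to 1241 with array weights and to 1 without control 3.

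Combined minus radiation asked what simvastatin changed in irradiated lungs. By limma 0 of 11602 genes passed, with 518 at an unadjusted p under 0.05, and the lowest adjusted p was 0.835. Tlr1, a receptor for bacterial lipoproteins, differed by 1.09 ± 0.23, and the uncharacterised gene 4930486L24Rik by -1.95 ± 0.41. Mzb1, which antibody-secreting cells need, was 9.09 ± 0.65 in the combined group and 7.07 ± 0.52 in the radiation group, a difference of 2.02 ± 0.44. The antiproliferative gene Tob2 differed by 0.69 ± 0.16 and the muscle kinase gene Srpk3 by 2.39 ± 0.60. These are the 5 genes of lowest p, each with a limma adjusted p of 0.835. By exact permutation, two-sided, Cdkn1a differed by -0.79 with p = 0.3 and the mean of the cholesterol list by -0.25 with p = 0.2. In the same exact permutation test the mean of the p53 list differed by -0.44 with p = 0.1, the lowest possible, and the array labelled combined 3 carried the low Cdkn1a value.

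Of 25 lists 14 passed at the preset correlation and 0 with an estimated correlation or by fry. B and plasma cell markers rose by a median of 1.17 with 14 of 14 members above 0 (adjusted p = 4.97e-17; adjusted p = 0.337 with an estimated correlation). Adjusted over the list alone 6 members passed and over all genes 0. Among the 6 were Mzb1, Cr2 at 1.84 ± 0.51, the B cell adaptor gene Blnk at 1.18 ± 0.35 and Ighm, the heavy chain of IgM, at 2.83 ± 0.87. The list stood at 0.078, 1.30 and 0.42 on the combined arrays and at -1.15, -0.50 and -0.25 on the radiation arrays. T and NK cell markers rose with it by 0.81 (adjusted p = 0.0119, and 0.682 with an estimated correlation). Erythroid markers, of which 3 of 13 were measured, rose by 0.87 (adjusted p = 0.0159, and 0.682 with an estimated correlation). Among them Alas2, an enzyme of haem synthesis, was at 1.56 ± 0.83. Thymocyte markers had a median of 1.12, and 0 members of either of these lists passed over the list alone. The T and NK median was 0.34 without combined 1 and the erythroid one 0.15 without combined 2.

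Every other list called in this comparison had adjusted p = 0.682 with an estimated correlation and 0 members passing over the list alone. Adipose markers rose by 2.07 (adjusted p = 9.16e-05), with Pck1, an enzyme of glycerol synthesis in fat, at 3.42 ± 1.96 and the fat hormone gene Adipoq at 2.23 ± 1.38. Brown fat markers had a median of 2.63, squamous epithelium markers of 2.82 (2.70 with low values set to a floor of log2 2.38), and skeletal muscle markers of 1.17 (adjusted p = 0.0671). Cardiac muscle markers rose by 0.42 (adjusted p = 0.0119) and cell cycle genes by 0.39 (adjusted p = 0.0159). The p53 target genes fell by 0.46 (adjusted p = 0.035), with 21 of 25 members below 0, the cell cycle inhibitor gene Rprm at -1.0 ± 0.48 and the death gene Pmaip1 at -0.96 ± 0.52. Their level was lower on the array labelled combined 3, at -0.40, than on combined 1 and combined 2, at 0.081 and 0.088. Alveolar type 2 markers fell by 0.26 (adjusted p = 0.0488) and alveolar type 1 markers by 0.40 (adjusted p = 0.0338), with Rtkn2, a gene of these thin gas-exchange cells, at -0.88 ± 0.45. Without combined 1 the median was -0.030 for cell cycle genes and -0.17 for alveolar type 2 markers, and without combined 3 it was -0.23 for p53 target genes.

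Another 5 lists passed upward here, again with adjusted p = 0.682 with an estimated correlation, and their medians fell below 0 under median centring because the median of all genes fell with them. They stayed above that median and were still called upward. MHC class II genes went from 0.23 (adjusted p = 0.00442) to -0.13, with H2-Ob at 1.28 ± 0.54. Interferon-stimulated genes went from 0.27 (adjusted p = 0.0169) to -0.086, with the antiviral gene Mx1 at 2.38 ± 1.02 and the peptide transporter gene Tap1 at 0.77 ± 0.31. Extracellular matrix genes went from 0.33 (adjusted p = 0.0149) to -0.026, with Lox at -1.32 ± 0.50 and the collagen-binding Dcn at 0.83 ± 0.34. Airway epithelial markers went from 0.13 (adjusted p = 0.0434) to -0.23, beside ciliated cell markers at a median of -0.24. Immediate early and heat shock genes, which respond to tissue handling, went from 0.21 (adjusted p = 0.0169) to -0.15. As deposited but without radiation 1, the medians were 0.0023 for MHC class II, -0.016 for matrix and 0.12 for immediate early genes. Interferon-stimulated genes were at 0.0052 without combined 1 and airway markers at -0.019 without combined 3. Cholesterol biosynthesis (adjusted p = 0.0712) and sphingolipid genes (adjusted p = 0.0925) did not pass, with medians of -0.28 and -0.22, Lss, which closes the sterol rings, at -0.66 ± 0.36 and Sphk1 at -0.90 ± 0.49. Inflammatory mediators had a median of 0.45 (adjusted p = 0.0671) and the glucocorticoid list of -0.33 (adjusted p = 0.0802), with Fam107a at -1.90 ± 0.79. The macrophage list had a median of -0.067 but a mean of 0.024 (adjusted p = 0.439), and the Nrf2 list a median of -0.059 while camera pointed up (adjusted p = 0.18).

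The share of the radiation change left with simvastatin could not be read from these arrays. Genes chosen without 1 radiation and 1 control array showed a radiation change of 0.022 ± 0.42 (SD over 9 choices) on the arrays left out. That mean averages values that differed with the control left out. They were 0.33 to 0.63 for control 1, -0.032 to 0.035 for control 2 and -0.80 to -0.091 for control 3. The 9 choices reuse the same arrays, so the SD is not one of independent values. Of the 9 choices 6 had no gene past the threshold. Over all genes the effect of radiation and that of adding simvastatin correlated at r = -0.70, where shared radiation arrays alone gave r = -0.50 ± 0.025 (SD of 100 simulated draws). The draws take genes as independent, so this SD is too small. Leaving out 1 array moved the excess both ways. It was smaller without combined 2 (-0.53 against -0.45), control 1 (-0.56 against -0.44) and radiation 2 (-0.70 against -0.60). It was also smaller without radiation 1, radiation 3 and, slightly, control 2. It was larger without combined 3 (-0.71 against -0.45), control 3 (-0.68 against -0.45) and combined 1 (-0.68 against -0.44).

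Of the 14 calls, B and plasma cell, cardiac muscle and adipose markers were kept in all 14 other settings, and those of p53 target genes and alveolar type 2 markers were kept in 6 each. The p53 call ended under 5 of the settings that keep all arrays, among them both scalings, and without the 3 Cdkn1a arrays, radiation 3 or combined 3. The alveolar type 2 call ended with 12 separate arrays and the alveolar type 1 call under median centring. Leaving out 1 array moved 10 of the 14 medians by over 1.5 times and changed the sign of 3. The count of lists was 7 without radiation 1 and 9 without combined 2, and the gene count went from 0 to 1172 with array weights.

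Simvastatin minus control asked what the drug changed without radiation, with 2 samples against 3. By limma 0 of 11602 genes passed, with 214 at an unadjusted p under 0.05, and the lowest adjusted p was 0.99. Ints1, a subunit of the complex that processes small nuclear RNAs, differed by -1.15 ± 0.26, and Errfi1, a feedback inhibitor of the EGF receptor, by 1.45 ± 0.35. The ring finger gene Rnf227 differed by -1.85 ± 0.45, the receptor-trafficking gene Arrdc3 by 0.86 ± 0.21 and Mbd1 by 0.69 ± 0.18. These are the 5 genes of lowest p, each with a limma adjusted p of 0.99. Cdkn1a differed by 0.92 (exact permutation, two-sided p = 0.5), and the array labelled simvastatin 2 carried its high value.

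Of 25 lists 13 passed at the preset correlation and 0 with an estimated correlation or by fry. The median of skeletal muscle markers fell by 6.02 with 11 of 11 members below 0 (adjusted p = 1.57e-11; adjusted p = 0.619 with an estimated correlation). Adjusted over the list alone 9 passed and over all genes 0, with Acta1 at -9.37 ± 3.09 and the creatine kinase gene Ckm at -4.48 ± 1.58. The fast troponin gene Tnnc2 lay under the floor of log2 2.38 on the simvastatin arrays, so its difference is a bound, at least as low as -10.71 with values set to that floor, and the median of the list was the same there. Squamous epithelium markers at -5.18 (-5.16 with the floor) and brown fat markers at -2.98, neither of them lung cells, moved with them. Cell cycle genes fell by 1.68 (adjusted p = 4.04e-08; adjusted p = 0.714 with an estimated correlation) and T and NK cell markers by 1.48 (adjusted p = 0.0273; adjusted p = 0.748 with an estimated correlation), beside thymocyte markers at -2.52. Interferon-stimulated genes fell by 0.39 (adjusted p = 0.0273; adjusted p = 0.748 with an estimated correlation). For these 3 lists 0 members passed over the list alone. Without control 1 the median was 0.11 for T and NK markers, which were then called upward, and -0.28 for cell cycle genes. Without control 3 it was -0.21 for interferon-stimulated genes.

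Endothelial markers rose by 0.47 with 21 of 22 members above 0 (adjusted p = 4e-07; adjusted p = 0.714 with an estimated correlation), led by Vwf, the clotting factor that endothelium stores, at 1.06 ± 0.32. Their level was -0.88, 0.46 and -0.23 on the controls and 0.19, 0.35 and 0.15 on the simvastatin arrays, so control 2 stood above all of these, and the median was 0.13 without control 1 and 0.91 without control 2. Cholesterol biosynthesis fell by 0.20 with 17 of 20 members below 0 (adjusted p = 0.0153; adjusted p = 0.723 with an estimated correlation), with Dhcr7, the last enzyme of the pathway, at -1.28 ± 0.39 and the squalene synthase gene Fdft1 at -0.55 ± 0.28. The exact permutation test of the mean of that list gave -0.24 and a two-sided p of 0.3, and without control 3 the median was -0.11. The glucocorticoid list rose by 0.35 (adjusted p = 0.00034; adjusted p = 0.619 with an estimated correlation), and over the list alone 3 passed: Errfi1, Tsc22d3 at 1.29 ± 0.39 and Sgk1 at 0.64 ± 0.20. Its median was 0.13 without control 2.

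Airway epithelial markers rose by 0.61 (adjusted p = 0.00123), neutrophil markers by 1.38 (adjusted p = 0.00123), alveolar type 2 markers by 0.21 (adjusted p = 0.00269), sphingolipid genes by 0.098 (adjusted p = 0.0216) and p53 target genes by 0.35 (adjusted p = 0.0247). Each had adjusted p = 0.714 with an estimated correlation and 0 members passing over the list alone. The ceramidase gene Acer2 was at 1.14 ± 0.39 and Perp, a p53 target that also holds squamous cells together, at -1.73 ± 0.76. Neutrophil markers were high on simvastatin 2, at 2.16 above the mean of 12 arrays, and at -0.95 and -1.06 on the other two, and without simvastatin 2 their median was -0.13. Airway markers were low on simvastatin 2, at -0.57 against 0.63 and 0.54, and their median was 0.16 without control 2 and 1.44 without simvastatin 2. Ciliated cell markers had a median of 1.21, with simvastatin 2 at -0.61 against 0.78 and 0.77. The p53 list stood at 0.36 on the array labelled simvastatin 2 and at -0.38 and -0.20 on the others, and its median was -0.15 without simvastatin 2. Without control 1 the alveolar type 2 median was -0.0023 and the sphingolipid one -0.029. Extracellular matrix genes had a median of 0.021, a mean of -0.035 and -0.062 under median centring, and did not pass (adjusted p = 0.934), and neither did Nrf2 target genes, at -0.011 with a mean above 0 (adjusted p = 0.814). MHC class II genes had a median of 0.0013 and a mean below 0 (adjusted p = 0.9).

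Of the 13 calls, only that of skeletal muscle was kept in its direction in all 14 other settings, while p53 target genes were kept in 8 and sphingolipid genes in 6. Both of these calls ended with 12 separate arrays, the test fixed beforehand. Leaving out 1 array moved 11 of the 12 medians reported by over 1.5 times and changed the sign of 5. The endothelial and glucocorticoid calls ended when the arrays with Cdkn1a against the label were left out, the cell cycle call without control 1 and the airway call without control 2. A fit of the compared groups alone called 13 genes, all lower, among them Acta1 and Tnnc2.

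Combined minus control asked how far lungs given both treatments lay from untreated lungs. By limma 0 of 11602 genes passed, with 327 at an unadjusted p under 0.05, and the lowest adjusted p was 0.995. The genes of lowest p were Mbd1 at 0.73 ± 0.16, the kinase gene Csnk2a1 at -0.76 ± 0.17, Gfpt2, which feeds glucose into glycosylation, at 1.56 ± 0.35, Mzb1 at 1.79 ± 0.44 and Ell2, an elongation factor of antibody-secreting cells, at 0.71 ± 0.18. Each had a limma adjusted p of 0.995. Cdkn1a differed by 1.20 (exact permutation, two-sided p = 0.2), with the arrays labelled control 3 and combined 3 against the direction of the other 4.

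Of 25 lists 13 passed at the preset correlation and 0 with an estimated correlation or by fry, and adjusted p = 0.656 with an estimated correlation for each list in this paragraph. The glucocorticoid list rose by 0.94 (adjusted p = 2.96e-06), airway epithelial markers by 1.05 (adjusted p = 9.43e-05) beside ciliated cell markers at 1.39, and neutrophil markers by 1.48 (adjusted p = 0.00386). B and plasma cell markers rose by 0.54 (adjusted p = 1.69e-05), where 1 member, Mzb1, passed over the list alone and the antibody joining chain gene Jchain was at 3.32 ± 1.05. Inflammatory mediators rose by 0.83 (adjusted p = 0.00154), with the B cell chemokine gene Cxcl13 at 2.48 ± 1.26. Macrophage markers rose by 0.32 (adjusted p = 0.01), with the scavenger receptor gene Marco at 2.24 ± 1.15, and Nrf2 target genes by 0.18 (adjusted p = 0.0117), with the NADPH-producing Me1 at 0.98 ± 0.42. Cholesterol biosynthesis fell by 0.16 (adjusted p = 0.0117), with the sterol carrier gene Stard4 at -0.63 ± 0.28. Erythroid markers, of which 3 of 13 were measured, rose by 0.91 (adjusted p = 0.0234), their level being 2.03 on combined 2 and at most 0.11 elsewhere. Without combined 2 the erythroid median was 0.19 and that of B and plasma cells 0.30. Without combined 1 it was 0.25 for inflammatory mediators, 0.029 for macrophages, 0.47 for the glucocorticoid list and -0.078 for cholesterol biosynthesis. Without control 1 it was 0.61 for neutrophils and -0.019 for Nrf2 target genes, and without control 2 it was 0.39 for airway markers.

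Adipose markers rose by 1.39 (adjusted p = 0.0117; adjusted p = 0.656 with an estimated correlation), with brown fat markers at 0.31. Cardiac muscle markers rose by 0.68 (adjusted p = 0.0314; adjusted p = 0.746 with an estimated correlation). Cell cycle genes fell by 0.79 with 22 of 22 members below 0 (adjusted p = 0.000797; adjusted p = 0.735 with an estimated correlation), beside thymocyte markers at -1.01 and squamous epithelium markers at -0.91. Apart from Mzb1, 0 members of the lists named for this comparison passed over the list alone. The p53 target genes did not pass (adjusted p = 0.0853) and had a median of 0.21. Without control 2 the median was -0.034 for adipose and -0.36 for cardiac muscle markers, and without control 1 it was 0.56 for cell cycle genes, so the calls of cardiac muscle and cell cycle turned over.

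Of the 13 calls, airway, neutrophil and glucocorticoid lists were kept in all 15 other settings, and the erythroid call was kept in 7. Leaving out 1 array moved all 12 medians reported by over 1.5 times and changed the sign of 4. Without control 3 the count of lists was 7 and that of genes 1, the B cell and inflammatory calls ended, and with array weights 43 genes passed.

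The interaction asked whether simvastatin changed irradiated lungs otherwise than unirradiated ones. By limma 0 of 11602 genes passed, with 377 at an unadjusted p under 0.05, and the lowest adjusted p was 0.882. The genes of lowest p were Arrdc3 at -1.23 ± 0.29, the muscle and B cell transcription factor gene Mef2c at 1.22 ± 0.30, the tropomyosin gene Tpm1 at 1.47 ± 0.37, Slc38a4 at -1.93 ± 0.49 and Mbd1 at -0.91 ± 0.24, each with a limma adjusted p of 0.882. Dhcr7 differed by 1.54 ± 0.53, Acta1 by 10.14 ± 4.15 and Cdkn1a by -1.71 ± 1.24, each with a limma adjusted p over 0.05, and for Cdkn1a the arrays labelled control 3, combined 3 and simvastatin 2 all enter. Of 25 lists 15 passed at the preset correlation and 0 with an estimated correlation or by fry. The glucocorticoid list fell by 0.82 (adjusted p = 0.000392; adjusted p = 0.534 with an estimated correlation), and 5 members passed over the list alone, among them Tsc22d3 at -1.93 ± 0.52, Sgk1 at -0.94 ± 0.27, Fam107a at -3.38 ± 1.19 and Errfi1 at -1.37 ± 0.47. In the other lists called 0 members passed over the list alone. Skeletal muscle markers rose by 7.74 (adjusted p = 6.79e-09; adjusted p = 0.534 with an estimated correlation), while squamous epithelium markers had a median of 7.59, brown fat markers of 5.67, thymocyte markers of 3.8 and ciliated cell markers of -1.47.

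Of the 15 calls, those of B and plasma cell, skeletal muscle and adipose markers and of cell cycle genes were kept in all 20 other settings, that of MHC class II genes ended under median centring, and that of cardiac muscle ended with 12 separate arrays. Leaving out 1 array moved 12 of the 14 medians reported by over 1.5 times and changed the sign of 1. If combined 3 holds the RNA of simvastatin 1 and 3, that RNA stands on both sides of this comparison and the samples are overcounted. Without combined 3 the counts were 0 genes and 12 lists. Without control 3 the count of genes was 1, and the p53 call ended without combined 3 and without simvastatin 2.

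Irradiated minus unirradiated asked what radiation changed on average over the drug's absence and presence. Such an average does not show a change in both, and the 2 can go in opposite directions. Skeletal muscle markers, for example, had a median of -2.69 in radiation minus control and 1.31 here. By limma 0 of 11602 genes passed, with 151 at an unadjusted p under 0.05, and the lowest adjusted p was 0.999. The genes of lowest p were F3 at 0.72 ± 0.15, Mbd1 at 0.50 ± 0.12, Cth at 0.78 ± 0.20, the heparan sulphate enzyme gene Hs3st3b1 at 0.64 ± 0.18 and the antibody gene Ighg3 at 3.37 ± 0.95, each with a limma adjusted p of 0.999. Of 25 lists 9 passed at the preset correlation and 0 with an estimated correlation or by fry, and 0 members of any list called passed over the list alone. The glucocorticoid list rose by 0.84 with 12 of 12 members above 0 (adjusted p = 2.13e-08; adjusted p = 0.361 with an estimated correlation), with Fam107a at 1.87 ± 0.59, the metal-binding Mt1 at 0.92 ± 0.28 and Tsc22d3 at 0.79 ± 0.26.

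The other 8 lists had adjusted p = 0.845 with an estimated correlation. Circadian clock genes rose by 0.43 (adjusted p = 0.0122), with the clock repressor genes Per2 at 1.36 ± 0.55 and Nr1d1 at 1.17 ± 0.46. The p53 target genes rose by 0.29 (adjusted p = 0.0165), with Cdkn1a at 1.13 ± 0.62 and Eda2r at 1.76 ± 0.99, against the levels of the arrays labelled control 3, combined 3 and simvastatin 2. Nrf2 target genes, which defend against oxidants, rose by 0.16 (adjusted p = 0.0165), inflammatory mediators by 0.54 (adjusted p = 0.0165) and skeletal muscle markers by 1.31 (adjusted p = 0.0473), beside squamous markers at 0.64 (0.60 with the floor), brown fat markers at 0.72 and ciliated cell markers at 0.83. T and NK cell markers fell by 0.53 (adjusted p = 0.00271), cell cycle genes by 0.25 (adjusted p = 0.0122) and MHC class II genes by 0.095 (adjusted p = 0.0172), beside thymocyte markers at -0.44. Without control 1 the median was 0.28 for T and NK markers, 0.45 for cell cycle genes, which were then called upward, 0.099 for Nrf2 target genes and 0.26 for the clock. Without radiation 1 it was 0.025 for MHC class II genes and 0.76 for skeletal muscle, and without combined 1 it was 0.33 for inflammatory mediators.

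Of the 9 calls, the glucocorticoid list was kept in all 20 other settings, the skeletal muscle call was kept in 8 and ended under median centring and with 12 separate arrays, and without control 3 the gene count was 1. If combined 3 holds the RNA of simvastatin 1 and 3, that RNA stands on both sides here too, and without combined 3 the counts were 0 genes and 9 lists. Among 3384 probe sets without a single gene symbol 0 passed by limma in any of the 6 comparisons, with a lowest adjusted p of 0.283 for combined minus radiation.

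**Figure D3:**
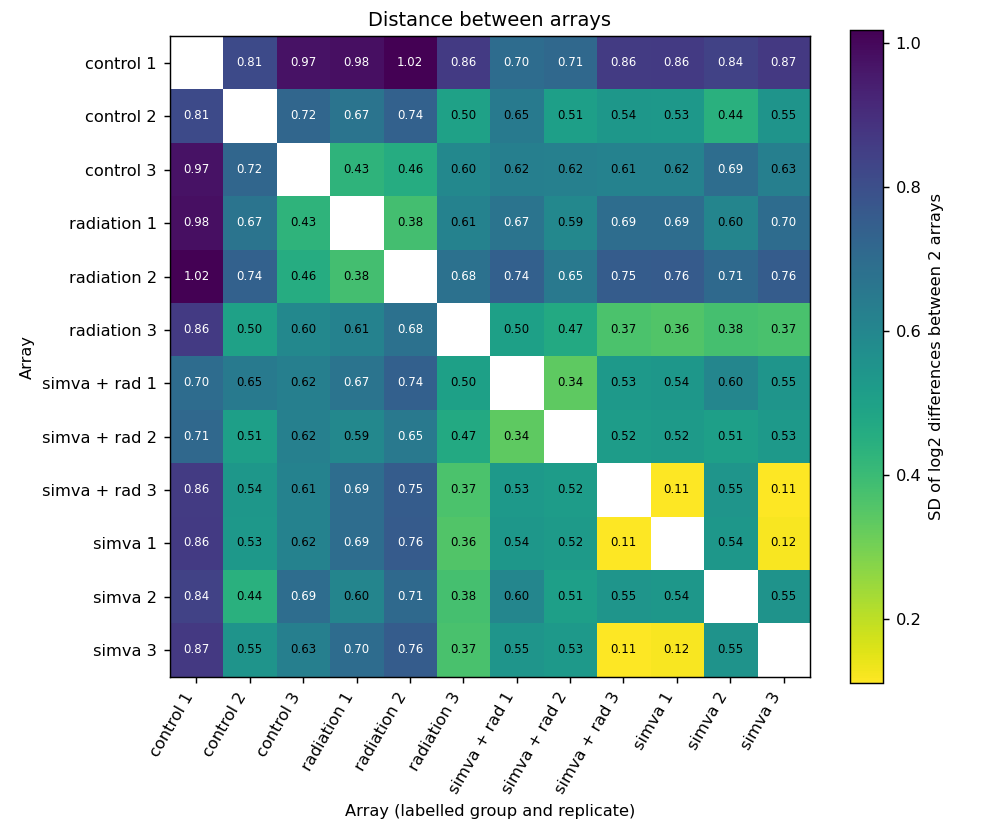
SD of log2 differences between each of the 66 pairs of arrays, over 10342 probe sets with a mean above 9. Combined 3, simvastatin 1 and simvastatin 3 differed by 0.111 to 0.118.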

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

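The tests of explanations in this part were chosen after the results were seen. The gene lists and the interaction test were chosen before. What marked the 14 lists below for a closer look is a difference between groups: the effect of simvastatin in irradiated lungs was not its effect in unirradiated lungs by the interaction test at the preset correlation, while with an estimated correlation 0 of them passed, with adjusted p from 0.534 to 0.628.

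Below 0, the medians of the interaction were -0.68 for p53 target genes (adjusted p = 0.00215), -0.42 for sphingolipid genes (adjusted p = 0.00528) and -0.60 for endothelial markers (adjusted p = 0.000234). They were -0.44 for alveolar type 2 markers (adjusted p = 0.000702), -0.47 for alveolar type 1 markers (adjusted p = 0.0149) and -0.82 for the glucocorticoid and fasting response (adjusted p = 0.000392). Above 0, they were 7.74 for skeletal muscle (adjusted p = 6.79e-09), 0.53 for cardiac muscle (adjusted p = 0.013), 2.63 for adipose markers (adjusted p = 0.000285), 2.04 for cell cycle genes (adjusted p = 3.41e-08) and 1.87 for T and NK cell markers (adjusted p = 0.000637). They were 1.11 for B and plasma cell markers (adjusted p = 9.89e-08), 0.45 for interferon-stimulated genes (adjusted p = 0.0014) and 0.23 for MHC class II genes (adjusted p = 0.0367), which became -0.13 under median centring because the median of all genes fell by as much, and were not called there. Without control 1 the medians were -0.00012 for alveolar type 1, -0.24 for alveolar type 2, -0.30 for endothelial, 0.49 for T and NK and 1.56 for adipose markers, -0.24 for sphingolipid genes and 0.79 for cell cycle genes. Without simvastatin 2 they were -0.17 for cardiac muscle and -0.39 for p53 target genes, without radiation 1 0.00097 for MHC class II, without combined 1 0.083 for interferon-stimulated genes and without combined 2 0.73 for B and plasma cells. The estimated adjusted p was 0.586 for endothelial markers, 0.628 for alveolar type 1, cardiac muscle and MHC class II lists, and 0.534 for the others.

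The levels of p53 target genes on control 3, combined 3 and simvastatin 2 go against their labels, and 3 technical explanations were tested, the distances with that list left out. An exchange of combined 3 with simvastatin 2 stayed open: the SD of log2 differences of combined 3 to simvastatin 1 and 3 averaged 0.112, under 0.336, the lowest of other pairs, but simvastatin 2 lay at 0.544 from simvastatin 1 and 3 and at 0.554 from combined 1 and 2, and closest to radiation 3 (0.379) and control 2 (0.435), an exchange with which was not tested. A wrong label of control 3 stayed open too: it lay at 0.493 from the radiation arrays and at 0.846 from the other controls. Yet it lay closest to radiation 1 and 2 (0.427 and 0.458), which share its side of the first principal component, and at 0.596 from radiation 3. Control 3 and radiation 1 are also the 2 arrays with Y-linked transcripts, and what this adds to the distances was not tested. Skeletal muscle in the piece as the whole cause is argued against, on 1 array each of 2 groups. Both had less of it than the rest of their groups, with the muscle list at -1.26 ± 0.37 on control 3 and -7.01 ± 1.14 on combined 3 (SE of 11 members). Yet the p53 list was higher on control 3 by 0.87 ± 0.28 (SE of 25 members) and lower on combined 3, at -0.75 ± 0.25. These arrays were picked for their p53 direction, so only the shared muscle direction bears on the question. Each SE is over genes of 1 array and measures no spread between arrays. No biological explanation was tested.

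Combined 3, simvastatin 1 and simvastatin 3 were near-identical across 2 labelled groups. That 1 RNA was put on 3 arrays fits: 19 probe sets for immunoglobulins, which vary from animal to animal, differed by an SD of at most 0.198 among them. Separate animals made alike by a shared batch or by the normalization is argued against, because the same probe sets differed by 0.892 or more in all other pairs. Which of the labels belongs to that RNA was not tested.

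Transcripts of skeletal muscle, squamous epithelium and brown fat were high on part of the arrays. Tissue other than lung in the piece stays open: pairs of muscle markers had a median r of 0.971 over the 12 arrays, but any joint rise and fall gives such an r, and the squamous and brown fat genes were chosen after they were seen high on these arrays. An effect of radiation or drug stays open as part of the cause, and for skeletal muscle and squamous epithelium also as the whole. As the whole cause it is argued against for brown fat. Relative to the mean of 12 arrays, that list stood at 2.91, -1.62 and 2.82 on control 1, 2 and 3, which by their labels got neither treatment. Squamous markers stood at 5.05, 4.89 and -1.97 there, but that difference rests on control 3, whose label is in doubt. The radiation arrays with the highest and lowest level differed by 6.74 ± 2.97 (SD of 11 members) in muscle markers. That is 1 pair of arrays without the drug, and an unequal response to radiation would give such a difference too. Relative to the mean of 12 arrays, the muscle list stood between 1.34 and 3.36 on the controls. It stood between -3.75 and -3.42 on the simvastatin arrays, at 3.89 and 3.41 on combined 1 and combined 2, and at -3.42 on combined 3.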

How the results depend on the processing

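Chosen after results had been seen were the merging of simvastatin 1 and 3, the fits without the 3 Cdkn1a arrays, without the 2 arrays with Y-linked transcripts, with a block for the principal component, with gene-by-gene weights, with a block on control and combined arrays alone, median centring of lists, and leave-one-out of the correlation. Of the values under other settings that answer a comparison, 241 stayed within 1.5 times or within the spread, and 39 moved. Those that stayed include counts of 0 genes that remained 0, also under the 1.5-fold threshold, which cannot raise a count. A count of lists could stay while the lists called changed, so the 241 are no measure of stability. Unless a reason is given, the cause of a move was not tested. Since 0 named genes passed in any comparison, none had a call to lose or turn, and 54 of their values passed under another setting. Of the calls of lists, 4 turned to the other direction in 1 setting each: T and NK markers in simvastatin minus control and cell cycle genes in combined minus control and in the pooled comparison, without control 1, and cardiac muscle in combined minus control, without control 2.

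Array weights called 1241 genes in radiation minus control (889 up, 352 down), 1172 in combined minus radiation (396 up, 776 down) and 43 in combined minus control. Gene-by-gene weights called 790 in combined minus radiation and 0 elsewhere. Weights ran from 0.159 on control 1 to 3.54 on control 2. In simvastatin minus control, a fit of these groups alone called 13 genes.

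Without the 3 Cdkn1a arrays, a circular choice that leaves 1 simvastatin sample assumed to vary like the other groups, 9 genes passed in radiation minus control, 2 in combined minus control and 2 in the pooled comparison, and 5 lists in simvastatin minus control. Without the Y-linked arrays 1 gene passed in radiation minus control, and 7 lists in combined minus radiation. With median centring 12, 15, 13, 14, 15 and 11 lists passed in the order of the report. With the principal component block 7 lists passed in combined minus radiation and 4 in the pooled comparison. Estimated correlation and the direction test of fry left 0 lists in all 6 comparisons; a correlation between members of a list is what the former adds.

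Leaving out each array in turn gave 0 to 1 genes in radiation minus control, combined minus control, the interaction and the pooled comparison, always 1 without control 3, and 0 elsewhere. That gene was Aoc1, an amine-degrading enzyme, named after its value was seen. Lists ranged from 8 to 15 in radiation minus control, 7 (without radiation 1) to 18 in combined minus radiation with 9 without combined 2, 9 to 13 in simvastatin minus control, 7 (without control 3) to 16 in combined minus control, 11 to 17 in the interaction and 7 to 11 in the pooled comparison. The correlation of effects ranged from -0.76 without radiation 3 to -0.53 without combined 2. The held-out radiation change became 0.96 when genes were chosen and measured on the same arrays, which builds the difference in.

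With replicate number as a block, 0 genes passed anywhere and 12, 15, 10, 14, 14 and 11 lists in the order of the report, and the p53 call of combined minus radiation was among those that ended; 8 of 18 pairs of the same number had a correlation over 0.1, among them all 3 of control and combined arrays (0.318, 0.287 and 0.408), though not all of any other 2 groups. Those 2 groups alone with that block gave 0 genes and 15 lists, and each of the 13 was still called. With 12 separate arrays, the test fixed beforehand, 0 genes passed and 11, 13, 11, 14, 15 and 10 lists, and 5 list calls ended: p53 and sphingolipid genes in simvastatin minus control, alveolar type 2 in combined minus radiation, cardiac muscle in the interaction and skeletal muscle in the pooled comparison. There 610 in simvastatin minus control had an unadjusted p under 0.05. The filter asked for 3 of 12 arrays, so genes at background on part of the arrays stayed in and their differences are limited by it.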

Other observations

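The tests of gene counts over other splits were chosen after the result was seen, and those of list counts and of array weights before. For 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. In radiation minus control the labelled split gave 0 genes and another gave up to 280, and the lists were 11 against up to 14. In combined minus radiation they were 0 against 0 genes and 14 lists against up to 16, and in combined minus control 0 against up to 47 genes and 13 lists against up to 16. The split with 280 genes set control 1, control 2 and radiation 3 against the rest, which is the first principal component, so it points to a structure of the samples other than the labels.

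For irradiated minus unirradiated, 100 assignments of the 11 samples were counted. Of these 5 gave some genes, up to 292, where the labels gave 0, and 78 gave as many lists as the 9 of the labels, so chance cannot be excluded for these lists. With array weights estimated anew for each split, the labels gave 1241 genes in radiation minus control against up to 1849, 1172 in combined minus radiation against up to 1310, and 43 in combined minus control against up to 4045. In combined minus control the weights of 5 of the 10 splits stopped before they converged, among them the split with 4045 genes; all others converged. Of the 4 other splits that converged there, 3 gave as many genes as the labels, up to 1131. Whether a structure of the samples or the weighting itself gave these counts was not tested. What the counts of the splits that did not converge reflect was not tested either.

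Within the sides of the first principal component, radiation minus control for Cdkn1a was 0.24 with 1 control and 2 radiation arrays and 2.95 with 2 control arrays and 1 radiation array. The mean of the p53 list was 0.13 and 0.98, and that of the skeletal muscle list 0.59 and -6.76. The 1 control array on the first side is control 3, whose p53 target levels go against its label. The 0.24 and 0.13 therefore restate the level of that array and cannot show that the radiation change depends on the side.

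Nnt, a mitochondrial gene that is deleted in part in some C57BL/6 stocks, read between 10.6 and 12.6 on the 12 arrays. Mmp8, a neutrophil collagenase, read 12.1 on radiation 1 and 10.9 on simvastatin 2. The 2 measured mast cell markers ran from -1.0 on control 1 to 0.57 on simvastatin 2, relative to the mean of 12 arrays.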
